A study of Homo sapiens with 6 samples.

How the data were processed

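RNA was measured in TU-177 cells, an established human laryngeal squamous cell carcinoma line, 48 h after Lipofectamine transfection with a small interfering RNA against FSCN1 or with a control small interfering RNA. FSCN1 encodes fascin, an actin-bundling protein. Per the labels, 3 independent transfections were made for each of the 2 groups, and each of the 6 total RNA samples was labelled with Cy3 and hybridised to 1 one-colour Agilent human long noncoding RNA array.

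The deposited values are a single table of 163952 probes by 6 arrays. Scanner files were not used here. Agilent Feature Extraction 10.7.1.1 is named in the submitters' processing notes; the background correction, the filters and the normalization between arrays are not given in the sources used here. The deposited values were read as log2 intensities, since they run from 1.05 to 18.9 and only base 2 puts the highest within a scanner's range; the base itself is not given in the sources used here. Sorted from low to high, the 6 arrays hold nearly the same values, with a median gap to their mean of 3.4e-05 and a largest gap of 0.0717 on the log2 scale, which is the pattern that quantile normalization leaves. A shift of the whole RNA population between groups would not be visible in such values. All 6 arrays have a median of 4.81 and an upper quartile of 7.52. No detection call, background signal or saturation mark was used here, so a dim probe cannot be separated from background, and the number of arrays limits the precision.

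The probe IDs carry a 3-letter class and a number. No table used here pairs an ID with a gene or transcript, so the FSCN1 level, the genes, the long noncoding RNAs and the planned gene lists were not analysed here, and the meaning of the ID classes is not given in the sources used here. All comparisons were therefore made on probes. Several probes may report 1 transcript, so counts of probes are not counts of genes.

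Arrays were grouped by their titles. The planned test was fitted on all 163952 probes with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with 1 prior variance, no covariate), with the log2 difference taken as si-FSCN1 minus si-control. P-values were adjusted by Benjamini-Hochberg over all probes fitted, and a probe was called at an adjusted p under 0.05. The same fit on the 81976 probes whose mean over the 6 arrays lay above the median of 4.75 (the brighter probes, 50% of all) was an alternative fixed before the data were examined. Because the fit on all probes called none, the detailed description uses the brighter probes. Combinations of the other alternatives with this restriction were chosen after seeing the data.

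The rule for named items, fixed before the data were examined, took the largest differences among those past the threshold with at least a 2-fold change, non-overlapping groups and a mean above the median. It was applied to the brighter probes, and only the first 2 in each direction are printed, since an ID without a gene carries little information. Without any call over all probes, the rule falls back on the 5 smallest p-values in each direction. Of these, 4 of the 5 higher and 4 of the 5 lower lay below the median level, and they are not described.

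The alternatives fixed before the data were examined were quantile normalization, centring on the 75th percentile or on the median, leaving out the lower 50% or the lowest 25% of the probes by mean level, a prior variance that follows the level (trend), a robust prior, array weights, the replicate number as a block, and leaving out each array in turn. A test against a minimum 1.2-fold change (limma's treat) was added on probes. Whether equal replicate numbers pair the arrays was checked by correlating the deviations from the group means; the largest correlation over all probes was 0.001, so the numbers were not treated as pairs.

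The fits were tested on simulated data that kept the real probe means, with each probe's spread taken from the trend fit and 200 brighter probes changed. For the comparison of si-FSCN1 with si-control, the fit on all 163952 probes recovered 34% of probes changed 2-fold and 80% of probes changed 4-fold, and the fit on the 81976 brighter probes recovered 72% and 93%. The mean fitted differences were 0.999 and 2.00 on the log2 scale for these 2 fold sizes. Correlation between neighbouring probes and a larger spread in a single array were not simulated. The recovered shares are therefore not the power of the real comparison. Figures were drawn with matplotlib 3.10.9.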

Results

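Transcript levels were compared between TU-177 laryngeal carcinoma cells transfected with small interfering RNA against FSCN1 and cells transfected with control small interfering RNA, with 3 arrays per group. The series was set up to find which transcripts differ after knockdown of FSCN1. Each array gave a normalized log2 intensity for the same 163952 probes, in 8 classes of probe ID. The largest class, gmr, held 93627 probes, followed by gci with 21442, gmi with 13064, gnc with 12539, bnc with 11917, bmr with 9577, bmi with 1614 and bpr with 172. Since probes were not paired with genes, the level of FSCN1 itself was not analysed here, and the knockdown that the labels state is not checked by these values. All results are given for probes by their ID.

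Over all 163952 probes, no probe differed between si-FSCN1 and si-control at an adjusted p under 0.05 in limma's test, and the smallest adjusted p was 0.0759. At an unadjusted p under 0.05 there were 25573 probes, 13627 of them higher and 11946 lower in si-FSCN1, where 8198 would be expected by chance. The 3 arrays of one group lay entirely above or below the 3 of the other at 26.8% of the probes, where chance gives 10%. The count of 0 did not hold under each alternative: 2426 probes passed when the prior variance followed the level, 14381 with array weights, and 8455 without si-FSCN1 replicate 1. It stayed at 0 without any 1 of the other 5 arrays.

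Among the 81976 probes with a mean level above the median (the brighter probes), 2692 (3.28%) differed in limma's test at an adjusted p under 0.05. Of these, 1570 were higher and 1122 lower in si-FSCN1. Most of the differences were small: the higher probes had a median increase of 1.42-fold and the lower probes a median decrease of 1.44-fold. A change of at least 2-fold was found at 40 higher and 39 lower probes. The 3 arrays of each group did not overlap at any of them, which follows largely from choosing probes on adjusted p and fold. The count changed with each array left out. It rose to 15792 without si-FSCN1 replicate 1, with all 2692 kept, and the balance of directions then turned, to 7256 higher and 8536 lower. It fell to 1 without si-FSCN1 replicate 2, to 1 without si-FSCN1 replicate 3, to 0 without si-control replicate 1, to 1 without si-control replicate 2 and to 0 without si-control replicate 3. With arrays weighted by their agreement with their group, si-FSCN1 replicate 1 had the lowest weight, 0.285, and 29198 probes passed.

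**Figure D1:**
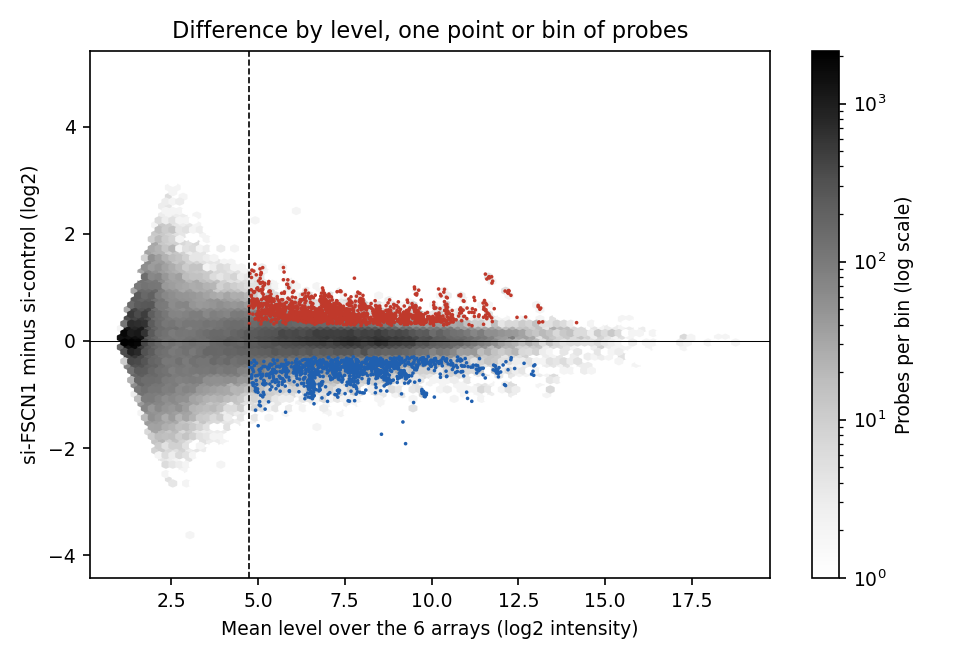
Difference between groups (vertical axis, si-FSCN1 minus si-control, log2) against mean level over the 6 arrays (horizontal axis, log2 intensity) for 163952 probes, shaded by number of probes per bin on a log scale. Coloured points are the 1570 higher (red) and 1122 lower (blue) probes called in the fit on brighter probes, to the right of the dashed line at 4.75. The spread is widest among dim probes, which were not part of that fit. In the fit over all probes no probe passed, dim or bright.

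The lower probe with the largest difference was hsa_bmr031078. Its level was 8.29 ± 0.037 (SD, n = 3) in si-FSCN1 and 10.21 ± 0.048 (SD, n = 3) in si-control, which is a 3.78-fold decrease (log2 difference -1.92, SE 0.062, limma adjusted p = 0.00196). Its 3 si-FSCN1 arrays lay within 8.26 to 8.34. The next lower probe was hsa_gci161430, at 7.69 ± 0.275 (SD, n = 3) against 9.43 ± 0.574 (SD, n = 3), a 3.34-fold decrease with a limma adjusted p of 0.0386. The 2 highest were hsa_gmr016946, which was 2.70-fold higher at 5.63 ± 0.229 against 4.19 ± 0.095 (limma adjusted p = 0.0146), and hsa_gmr082458, which was 2.59-fold higher at 6.42 ± 0.167 against 5.05 ± 0.329 (limma adjusted p = 0.0226), each with SD and n = 3 per group. The si-control level of hsa_gmr016946 lay below the 4.75 that bounds the brighter probes, where signal cannot be separated from background here, so its fold is that of the deposited values and not a measured ratio of transcript. In the fit over all probes the adjusted p-values of these 4 probes were 0.0759, 0.145, 0.0844 and 0.11 in the order named. In the 7 settings that could move the fitted difference (array weights and each array left out), hsa_bmr031078 passed in 5, with log2 differences from -1.94 to -1.88, and each of the other 3 passed in 2. The adjusted p of hsa_bmr031078 ran from 1.35e-05 to 0.144 over all alternative settings.

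**Figure D2:**
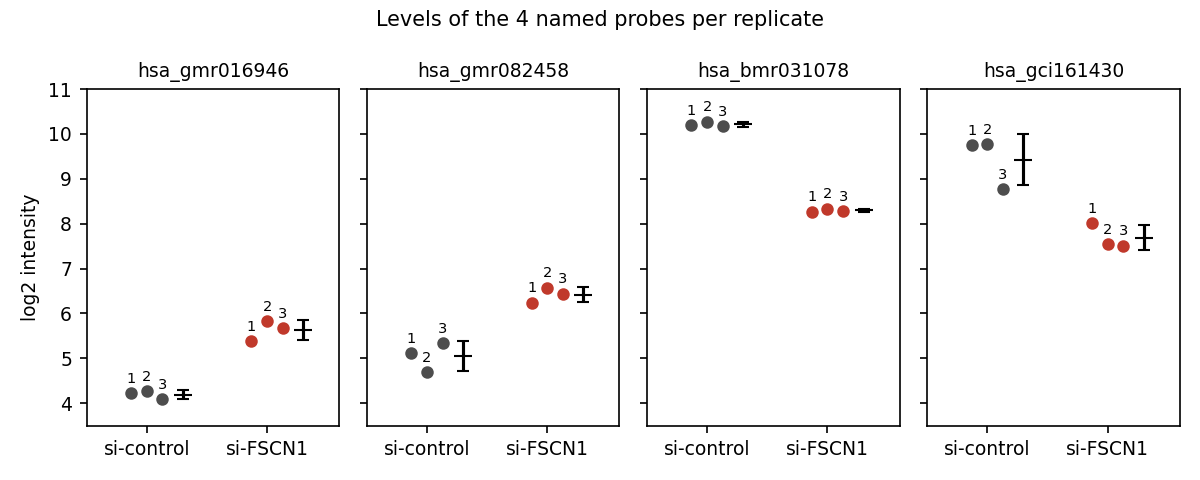
Levels (vertical axis, log2 intensity) of the 4 named probes in each array, labelled by replicate number, with mean ± SD beside each group of 3. The probes were chosen among those whose groups do not overlap, and hsa_bmr031078 has the smallest spread, with SDs of 0.048 and 0.037.

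Probe ID classes differed little in their median difference over all probes, which ran from -0.025 for bnc to 0.028 for gmi on the log2 scale. Among the brighter probes, the share that passed was 3.64% in gmr, with 1289 higher and 892 lower. It was 2.4% in gmi, with 136 higher and 77 lower, and 3.11% in bmr, with 69 higher and 63 lower. In gnc 2.6% passed, in bmi 2.06% and in bnc 1.88%. In gci, of which 12.4% were brighter probes, 0.938% passed, with 8 higher and 17 lower. In bpr 1 of 26 brighter probes passed. These shares were not tested against each other. Probes with consecutive ID numbers in 1 class moved alike, with a Spearman correlation across 54016 neighbouring pairs of 0.448 for the difference between groups, and of 0.194 to 0.345 for differences between 2 control arrays. Probes are therefore not independent of each other.

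The arrays of the si-FSCN1 group differed among themselves. Over the brighter probes, replicates 2 and 3 differed from each other with an SD of 0.222 over probes on the log2 scale, close to the 0.2 to 0.271 between control arrays. Replicate 1 differed from replicates 2 and 3 with SDs of 0.374 and 0.361, and from the 3 controls with smaller SDs of 0.287 to 0.334. When the changes of the arrays were measured against different controls, so that no control was shared, the covariance across probes was 0.0911 ± 0.0045 between replicates 2 and 3. It was 0.0221 ± 0.0012 between replicates 1 and 2 and 0.0256 ± 0.0012 between replicates 1 and 3, where errors are jackknife standard errors over 100 blocks of ID order. The mean of the pairs with replicate 1 was 0.262 ± 0.023 of that of replicates 2 and 3. Over the dimmer probes, those outside the brighter set, replicate 1 lay far from every other array, controls included, with SDs of 0.962 to 1.047. All pairs of arrays without replicate 1 gave SDs of 0.706 to 0.884 there. Whether si-FSCN1 replicate 1 is a noisier array was not tested.

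Without si-FSCN1 replicate 1, 119 brighter probes were at least 2-fold higher and 996 at least 2-fold lower at an adjusted p under 0.05 in limma's test. Of these 1115 probes, 68 were among the 79 that passed at 2-fold or more with all 6 arrays. Replicate 1, which entered the mean level that defines the brighter probes but not the test that chose the 1115, held a median of 0.11 of the log2 change of replicates 2 and 3 over them. A control array left out in its place, with replicate 1 then set among the controls, held a median of 0.088, -0.062 or 0.021 for si-control replicates 1, 2 and 3 over the probes so chosen. The part differed by direction. Among the 119 higher probes the median part was 0.536, with 48 probes at 0.75 or more of the change and 37 under 0.25. Among the 996 lower probes it was 0.092, with 23 probes at 0.75 or more and 798 under 0.25. The 3 controls enter both changes, which can raise these parts. The choice of probes by a large change in replicates 2 and 3 can lower them.

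**Figure D3:**
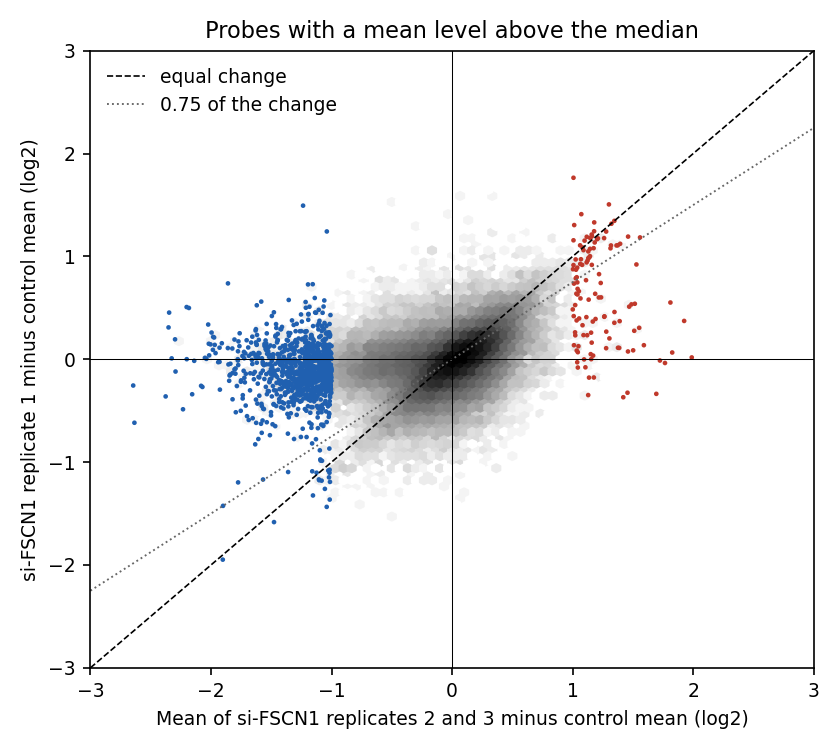
Change from the control mean in si-FSCN1 replicate 1 (vertical axis, log2) against the mean change in replicates 2 and 3 (horizontal axis, log2) for the brighter probes, shaded by number of probes per bin on a log scale; a few probes beyond the axes are not drawn. Of the 119 higher (red) and 996 lower (blue) probes called in the test without replicate 1, 48 and 23 lie at or beyond 0.75 of the change (dotted line), and most blue points lie near 0 on the vertical axis.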

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

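The gene-level, long noncoding RNA, gene list and FSCN1 alternatives planned before the data were examined, and the average over probes of a gene, were not run, since probes were not paired with genes. Over all probes the count of 0 called probes stayed at 0 under quantile normalization, both centrings, the robust prior, the lowest 25% left out, the minimum-fold test and the replicate block. It became 2692 with the lower 50% left out, 2426 with the trend and 14381 with array weights, and ranged from 0 to 8455 without each array in turn. The 25573 probes at an unadjusted p under 0.05 became 49905 with array weights and 7417 under the minimum-fold test, and ranged from 17077 to 43926 without each array. Among the brighter probes the 2692 called probes became 6176 with the trend (2479 of them shared with the 2692), 29198 with array weights (all 2692 shared), 32 under the minimum-fold test and 0 with the replicate block, and ranged from 0 to 15792 without each array. The 22010 brighter probes at an unadjusted p under 0.05 became 39286 with array weights and 3843 under the minimum-fold test, and ranged from 14131 (without si-FSCN1 replicate 3) and 14329 (without si-FSCN1 replicate 2) to 30253 (without si-FSCN1 replicate 1). The quantile, 75th percentile and median settings moved almost nothing because the deposited arrays already share their distribution, so they say nothing about stability. Same-numbered arrays did not deviate together (correlations of -0.061, -0.045 and 0.001 for replicates 1, 2 and 3 over all probes, and -0.211, -0.192 and -0.004 over the brighter probes), so the replicate block removes residual degrees of freedom without a known pairing, and the calls it ends are no sign of a weaker effect. A fit without 1 array leaves fewer degrees of freedom, and the cause of the fall to 0 or 1 calls was not otherwise tested. The 4 named probes, chosen for non-overlapping groups, could not change direction with array weights or an array left out. The signal over background is unknown, which limits the dimmer probes, where the median residual SD was 0.412 against 0.115 among the brighter probes.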

Other observations

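The tests in this part were chosen after the results they bear on were seen, with an exception fixed before the data were examined. It is the number of called probes per split in the fit over all probes, and not the number at an unadjusted p under 0.05. The fit with a trend was fixed beforehand as an alternative setting, but not as a test of the prior variance.

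Without si-FSCN1 replicate 1, the 996 lower probes made up 7.21% of the brighter gci probes (192), 4.62% of bnc (125), 4.56% of gnc (130) and 3.43% of bmi (25). They made up 1.74% of bmr (74), 1.00% of gmi (89) and 0.603% of gmr (361), with 0 of 26 in bpr. The 119 higher probes of the same fit included 77 of the 59877 brighter probes in gmr, 15 of 2848 in gnc and 8 of 2665 in gci. Another 7 of 4249 were in bmr, 6 of 2707 in bnc and 5 of 8876 in gmi. In bmi there was 1 of 728, and in bpr 0 of 26. The largest count, in gmr, thus came from the largest class. These shares were not tested, since neighbouring probes are correlated.

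The pattern most open to doubt is that si-FSCN1 replicate 1 lacks most of the large changes of replicates 2 and 3. A control array under the si-FSCN1 label is argued against, though not excluded, by the higher probes. Replicate 1 held at least 0.75 of the change at 40.3% of them (48 of 119). A control left out in its place, with replicate 1 set among the controls, did so at 4.44% at most (2 of 45 probes, from another choice of probes). At the lower probes replicate 1 did so at 2.31%, below the 4.82% of si-control replicate 1, as a control array would. It lay above the 0.122% of si-control replicate 2 and the 0.114% of si-control replicate 3, so the 2-fold lower probes of these fits do not decide. Neither does the median part over both directions, 0.11 in replicate 1 and 0.088 in si-control replicate 1. Over all brighter probes, replicate 1 set with replicates 2 and 3 against the other 3 arrays gave 1122 lower calls. With any 1 of the 3 controls in its place there were 0 calls. Ranking 1 array against 3 controls cannot give a share under 0.05, in this count or at the higher probes. A lower share of responding cells in replicate 1 would give 1 part of the linear change for all probes. The median part was 0.435 for higher and 0.134 for lower probes, a difference of 0.301 ± 0.106 (block bootstrap error). This was under the 3 errors set, after the result was seen, for excluding it. The test compared 2 medians only. The part also varied among the higher probes, with 48 of 119 at 0.75 or more of the log2 change and 37 under 0.25. That spread was not tested against the noise of 1 array, so this explanation stays open. A batch of cultures or arrays shared by replicates 2 and 3 cannot be told apart from a response to FSCN1 knockdown that replicate 1 lacks, since the labels give no batch and both predict the 835 probes with under 0.25 of the change in replicate 1.

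The second pattern is that no probe passed over all probes while 2692 of the brighter probes passed when fitted alone. With a prior variance that follows the level, 2426 probes passed over all probes, which is consistent with 1 prior variance for dim and bright probes being a source of the count of 0. The prior degrees of freedom rose from 1.29 to 2.31 with the trend and were 2.54 over the brighter probes.

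The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Over all probes, all 10 splits called 0 probes, as the real split did, and the real split was the 1 split with 25573 probes at an unadjusted p under 0.05, where the highest other split had 14076. Over the brighter probes the real split called 2692 probes, again the highest (1 of 10), and the highest other split called 0. Every other split mixes si-FSCN1 and si-control arrays on each side. A real difference then adds to the spread within sides and lowers the counts, so these low counts are partly built in. The split with 14076 probes set si-FSCN1 replicates 2 and 3 with si-control replicate 1 against the other 3 arrays.

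Single arrays also held isolated bright or dim probes. Among the brighter probes, 33 of si-FSCN1 replicate 1 lay more than 4-fold above all 5 other arrays, against 18 in si-FSCN1 replicate 2, 10 in si-control replicate 1, 5 in si-FSCN1 replicate 3, 3 in si-control replicate 2 and 1 in si-control replicate 3. The largest gap was 14.2 on the log2 scale, in si-FSCN1 replicate 2. More than 4-fold below all 5 other arrays lay 16 probes in si-FSCN1 replicate 2, 10 in si-control replicate 1 and 0 in each of the other 4 arrays. A single high value also raises a probe's mean level, which defines the brighter probes, so the counts above and below are not on equal terms.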
